A study of Mus musculus with 40 samples.

How the data were processed

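RNA-seq libraries of mouse (C57BL/6) kidney were analysed from 3 deposited tables of raw read counts, one each for the temporal, therapy and sham arms. Per the submitters' processing notes, reads were aligned to GRCm39 (mm39), counted per gene with HTSeq and compared with DESeq2. The aligner is not given in the sources used here, and neither is whether counting used strand. The deposited count values were whole numbers, and the authors' normalised values were not used here. The 40 samples filled 44 library columns, since the same 4 Control libraries stood in the temporal and therapy tables, and 0 columns were left unused.

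The tables held 258137 lines for the temporal arm, 258140 for the therapy arm and 56748 for the sham arm. The first 2 tables repeated lines for names held by several gene IDs, as a join by name does, and each name was taken once per library, which left 55862, 55866 and 55866 names. Where a name was held by several gene IDs (78, 77 and 77 names), their counts were added. The way repeated lines varied showed which columns had been joined. Control and IRI 6 h libraries came from one block and the 24, 48 and 72 h libraries from another, and AKI from another than Control, BM-MSC and UC-MSC. Control counts were compared name by name between the temporal and therapy tables, and 85 names were left out of both fits. Of these, 74 had differing Control counts, 6 stood in 1 of these tables, 4 shared another name's Control counts and 1 was repeated with different counts. They were kept in the sham fit. Gene positions were not used, since the annotation at hand was of another genome build, and genes were identified by the symbols of the tables. Near-identical copies such as Gapdh, Mt2 and Rpl24 and their pseudogenes are uncertain, as reads could be split between copies.

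Each arm was fitted with all its groups in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test (glmQLFit, glmQLFTest) after TMM scaling and filterByExpr. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. This left 16653 genes in the temporal arm, 16623 in the therapy arm and 17781 in the sham arm. The comparison of IRI 24 h with sham 24 h fitted both arms together (19616 genes) as a difference of differences, each against its own controls without surgery. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Means and SDs are of counts-per-million after TMM scaling in the 4 libraries of a group. Log2 CPM used a prior count of 2. Where all libraries of a group had no count, a fold is given as a bound against a floor of 3 counts over the group, which covers counting error only.

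Changes of 34 gene lists with 614 genes were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members called are given over all genes and adjusted over the list alone. Beside each list called by camera, the adjusted p with an estimated correlation is given. The lists, the comparisons, the tests, most alternatives and the rule for named genes were chosen before the data were examined. By that rule, the text could name the 8 largest rises and falls in log2 fold change of a main comparison (4 in other comparisons) among called genes with a mean log2 CPM of at least 3, separate ranges of the groups and a name that is not a predicted one. It could also name 24 sentinel genes, and for each list up to 4 called members with the largest change and up to 2 members not called.

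Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts (a minimum of 1 count), fits of 2 groups only, each library left out in turn, the replicate number as a block, and for lists camera with an estimated correlation and fry. After the data were examined, 3 alternatives were added, in which names with disagreeing counts were kept, IRI 6 h libraries took the place of AKI, and libraries were left out of the comparisons with IRI 6 h. Reversal of injury changes was set beside 20 simulated unchanged groups and all 6 ways of dividing the AKI libraries 2 and 2. Every count of genes called was set beside the 35 splits of its 8 libraries into 4 and 4, or 100 drawn regroupings for the comparison across arms (seed 1). Data were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

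The procedure was tested on simulated data with 200 genes changed by known folds, drawn from the real means and library sizes. For IRI 6 h against no surgery, 52% of genes changed 2-fold and 88% of genes changed 4-fold were called, with 4 false calls among 16653 genes. These shares were 59% and 98% for BM-MSC against AKI (8 false calls), 93% and 100% for sham surgery (9 false calls), 24% and 84% for IRI 24 h against sham 24 h (9 false calls) and 53% and 99% for BM-MSC against IRI 6 h (2 false calls). Depth per library ranged from 4640921 counts at 72 h to 37097091 in the unoperated sham controls, and the number of names with a count from 15694 to 24134.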

Results

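RNA of mouse kidney was sequenced after ischaemia-reperfusion injury (IRI), in which the renal blood supply is clamped and then released. A second arm added human mesenchymal stromal cells (MSCs) from bone marrow (BM) or umbilical cord (UC), which were injected right after reperfusion. The temporal arm held kidneys without surgery (Control) and kidneys taken 6, 24, 48 and 72 h after reperfusion. The therapy arm held Control, untreated injury (AKI), BM-MSC and UC-MSC groups, and the sham arm held unoperated kidneys and kidneys taken 24 h after surgery without ischaemia. Every group had 4 libraries, and the Control libraries of the temporal and therapy arms were the same 4. The labels do not state whether the replicates were separate animals. All p-values therefore measure only the spread between these samples, which may be technical.

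Total counts per library, over the names analysed, ranged from 14938484 to 16338711 in Control and from 13313097 to 17533712 at 6 h. They ranged from 6696400 to 13517430 at 24 h, from 5444724 to 7014133 at 48 h and from 4640921 to 5366202 at 72 h. AKI libraries held 15157068 to 18475869 counts, BM-MSC libraries 15397188 to 18181369 and UC-MSC libraries 12949029 to 15967232. The unoperated sham controls held 27792987 to 37097091 counts and the sham-operated libraries 26601247 to 34009719. With the names left out of the fits, Control library 1 held 20341209 counts in the temporal table in place of 16338711. A centrosomal protein gene, Cep85, took 0.0122% of the counts in Control, 0.977% at 24 h, 6.93% at 48 h and 11.4% at 72 h. The 10 most abundant of the names analysed together took between 7.90% and 8.82% of their counts in Control and between 25.8% and 29.3% at 72 h.

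Several genes central to kidney injury could be followed in the sham arm alone, because their counts disagreed between the temporal and therapy tables. For 74 of the 55861 names in both tables, or 0.1325%, the counts of the same Control libraries differed. With 11 others, 85 names were left out of the temporal and therapy fits. They held the tubular injury markers Havcr1 and Lcn2, the connexin 43 gene Gja1, the mitochondrial genes Sod2 and mt-Co1, the cytokines Il6, Il1b and Ccl2, and the proliferation marker Mki67. For 52 of the 74 names, the Control counts of the temporal table stood under another name in the therapy table. The columns also fell into joined blocks. Control and the 6 h libraries formed one block of the temporal table and the 24, 48 and 72 h libraries the other, while AKI stood apart from the other 3 groups of the therapy table. Differences between blocks cannot be told apart from a difference in how the blocks were made.

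At 6 h after reperfusion, genes of tubular injury rose while genes of the straight part of the proximal tubule fell. All 18 tested tubular injury genes rose (18 adjusted over the list alone), with a median log2 fold change of 2.95 (camera adjusted p = 4.9e-19, or 0.031 with an estimated correlation). Krt20, a keratin of injured epithelium, went from 9.49 ± 5.10 to 237 ± 254 counts-per-million (CPM, mean ± SD, n = 4 in each group). Its log2 fold change was 4.64 ± 0.60 (± SE, adjusted p = 6.1e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave every adjusted p of a single gene), or 3.54 without IRI 6 h library 1. Sox9, a transcription factor of tubular repair, rose from 1.49 ± 0.364 to 31.1 ± 7.67 CPM (4.37 ± 0.30, adjusted p = 1.2e-09), and the adhesion receptor Cd44 and the protease inhibitor Timp1 rose by 4.12 ± 0.35 and 4.97 ± 0.45. In the proximal tubule's S3 segment, the site most exposed to low oxygen, 13 of 14 genes fell (13 adjusted over the list alone, median −2.53, camera adjusted p = 5.9e-19, or 0.031 with an estimated correlation). The organic anion transporter Slc22a7 went from 496 ± 63.5 to 19.6 ± 8.25 CPM (−4.66 ± 0.27, adjusted p = 8.2e-11) and the hydroxylase Cyp7b1 from 383 ± 32.4 to 16.5 ± 4.48 CPM (−4.53 ± 0.33, adjusted p = 2.7e-09). In the S1 and S2 segments, 10 of 18 genes fell (12 adjusted over the list alone, median −0.93, camera adjusted p = 6.5e-09, or 0.13 with an estimated correlation). Among these, the phosphate transporter Slc34a1 fell (−1.53 ± 0.34, adjusted p = 0.0019), while the glucose transporter Slc5a2 did not pass (−0.92 ± 0.42, adjusted p = 0.14). In the thick ascending limb, 9 of 14 genes fell (9 adjusted over the list alone, median −0.91, camera adjusted p = 3.1e-06, or 0.060 with an estimated correlation), led by the growth factor gene Egf (−3.41 ± 0.28) and the cotransporter Slc12a1 (−2.34 ± 0.30).

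Genes of dividing cells, inflammation and stress rose at the same time. Of 24 cell cycle genes, 23 rose (24 adjusted over the list alone, median 3.60, camera adjusted p = 1.4e-20, or 0.052 with an estimated correlation), among them the mitotic kinase Plk1 (4.25 ± 0.51) and the survivin gene Birc5 (4.02 ± 0.47, adjusted p = 1.9e-06). Cytokine and chemokine genes rose in 12 of 18 cases (12 adjusted over the list alone, median 2.92, camera adjusted p = 1.2e-06, or 0.036 with an estimated correlation). The neutrophil attractant Cxcl2 went from 0.317 ± 0.262 to 43.4 ± 61.9 CPM (7.03 ± 1.05, adjusted p = 3.5e-05). Macrophage and monocyte genes gave 10 rises and 1 fall among 17 (10 and 1 adjusted over the list alone, median 1.39, camera adjusted p = 4.4e-06, or 0.031 with an estimated correlation), with the largest of the listed rises in the chitinase-like gene Chil3 (5.19 ± 0.54, adjusted p = 3.4e-07). Of 6 neutrophil genes, 4 rose (6 adjusted over the list alone, camera adjusted p = 0.0029, or 0.21 with an estimated correlation), S100a8 by 5.80 ± 0.79, adjusted p = 1.3e-05. Fibroblast and matrix genes rose in 12 of 16 cases (12 adjusted over the list alone, median 1.58, camera adjusted p = 2.3e-12, or 0.031 with an estimated correlation), including the collagens Col1a1 (2.74 ± 0.20) and Col3a1 (2.71 ± 0.22). Targets of the oxidative stress factor NRF2 gave 13 rises and 1 fall among 20 (13 and 4 adjusted over the list alone, camera adjusted p = 3.8e-05, or 0.14 with an estimated correlation). The haem oxygenase gene Hmox1 rose (2.68 ± 0.40, adjusted p = 3.3e-05). IRI 6 h library 1 held the highest Krt20, Hmox1 and S100a8 of its group, and without it Hmox1 rose by 1.76, S100a8 by 4.32 and Cxcl2 by 5.24.

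Genes of mitochondrial respiration fell as well. Of 52 nuclear genes of oxidative phosphorylation, 29 fell (36 adjusted over the list alone, median −0.41, camera adjusted p = 2.1e-13, or 0.074 with an estimated correlation), with Sdha of complex II at −0.86 ± 0.16, adjusted p = 0.00045. The biogenesis regulator PGC1a, encoded by Ppargc1a, did not pass (0.35 ± 0.22, adjusted p = 0.34), at 75.7 ± 1.79 CPM in Control and 96.2 ± 11.4 CPM at 6 h. Around it, 1 of the 18 biogenesis genes rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.020, or 0.10 with an estimated correlation). Pprc1 rose (1.26 ± 0.28, adjusted p = 0.0022), and the deacetylase gene Sirt3 (−1.18 ± 0.20, adjusted p = 0.00020) and the receptor gene Esrrg (−1.03 ± 0.32, adjusted p = 0.027) fell. Of 15 tested connexin and nanotube genes, the pannexin gene Panx1 rose (2.12 ± 0.71, adjusted p = 0.038) and the mitochondrial transport adaptor Trak2 fell (−0.71 ± 0.23, adjusted p = 0.035, 2 and 2 adjusted over the list alone, camera adjusted p = 0.62). Over all 16653 genes tested, 3141 differed from Control at 6 h, 1724 upward and 1417 downward, and 1092 and 593 of these differed by at least 2-fold. Leaving out IRI 6 h library 1 left 2288 genes, and fitting only these groups gave 7443. Mitochondrial ribosomal RNA took 0.205% to 0.444% of the counts, against 0.151% to 0.177% in Control.

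**Figure D1:**
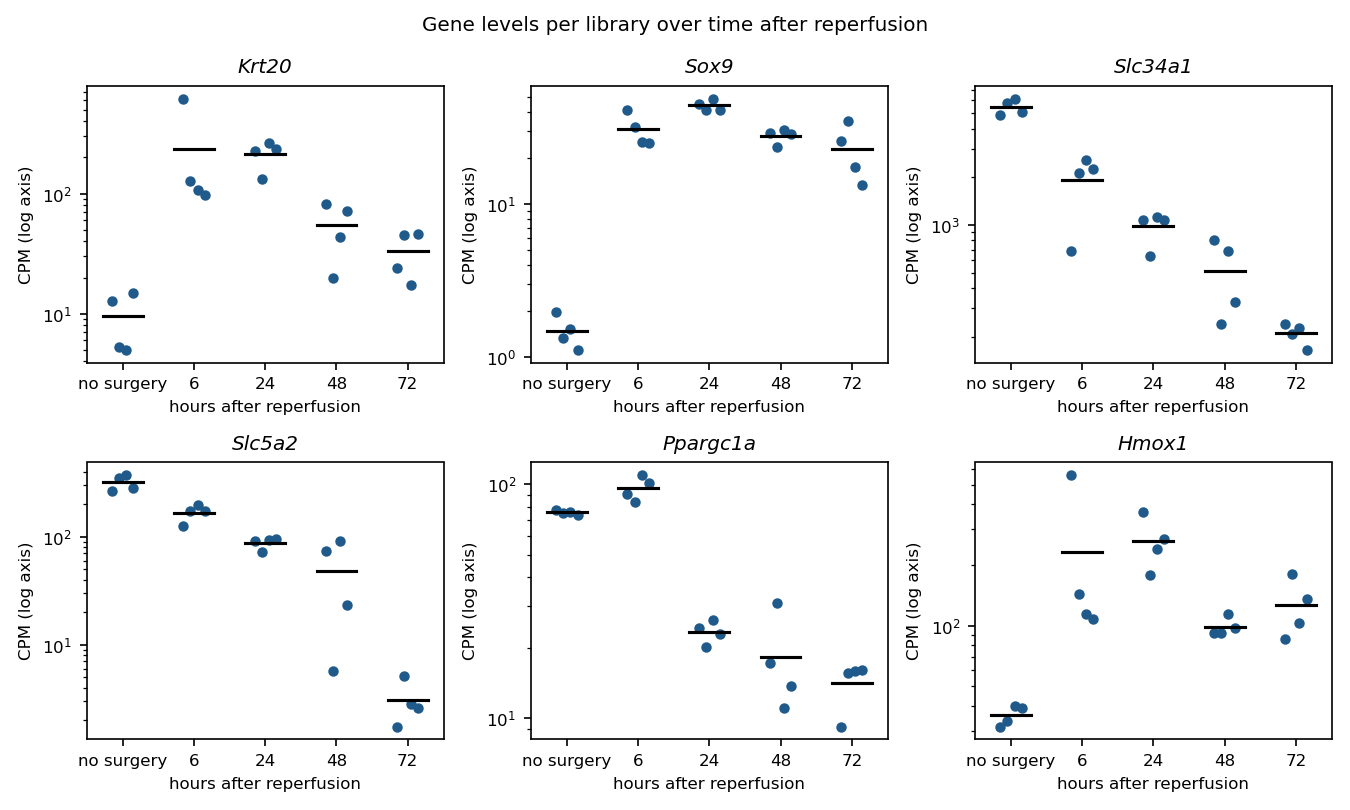
CPM (log axis) of Krt20, Sox9, Slc34a1, Slc5a2, Ppargc1a and Hmox1 in each library without surgery and 6, 24, 48 and 72 h after reperfusion, with bars at the mean of 4 libraries. Mean Slc5a2 went from 317 ± 51.8 CPM without surgery (mean ± SD) to 3.07 ± 1.45 CPM at 72 h, and Ppargc1a from 75.7 ± 1.79 to 14.2 ± 3.31 CPM.

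At 24 h genes of tubular function were lower than in Control along the nephron, and so was the PGC1a gene. Mitochondrial ribosomal RNA took 1.22% to 1.36% of the counts, against 0.151% to 0.177% in Control, so this share moved with these changes. Whether it reflects RNA preparation or the injury was not tested. All 18 S1 and S2 genes fell (18 adjusted over the list alone, median −2.61, camera adjusted p = 2.7e-12, or 0.16 with an estimated correlation). All 14 S3 genes fell too (14 adjusted over the list alone, median −3.83, camera adjusted p = 3.4e-12, or 0.13 with an estimated correlation). The creatine synthesis gene Gatm fell by 4.43 and the endocytic receptor gene Lrp2 by 3.91 on the log2 scale (SE 0.38 and 0.43). In the thick ascending limb, 10 genes fell and 1 rose of 14 (10 and 1 adjusted over the list alone, camera adjusted p = 5.5e-06, or 0.13 with an estimated correlation). Egf went from 1184 ± 131 to 11.3 ± 1.36 CPM (mean ± SD, n = 4 in each group, −6.71 ± 0.33, adjusted p = 3.7e-12), and the uromodulin gene Umod also fell (−3.15 ± 0.21, adjusted p = 1.4e-10). Tubular injury genes rose in 17 of 18 cases (17 adjusted over the list alone, median 3.47, camera adjusted p = 3.4e-12, or 0.13 with an estimated correlation), with Krt20 at 214 ± 58.2 CPM and Sox9 at 44.4 ± 3.71 CPM. Ppargc1a fell to 23.4 ± 2.51 CPM (−1.69 ± 0.23, adjusted p = 3.1e-06), as did its DNA-maintenance target Tfam (−1.06 ± 0.26, adjusted p = 0.0018) and Esrrg (−2.26 ± 0.34, adjusted p = 9.0e-06), while Pprc1 rose (1.94 ± 0.29). The biogenesis list as a whole gave 2 rises and 7 falls (2 and 8 adjusted over the list alone, camera adjusted p = 0.059). Fatty acid oxidation, the main fuel pathway of the proximal tubule, fell in 20 of 26 genes and rose in 1 (20 and 1 adjusted over the list alone, median −1.24, camera adjusted p = 5.6e-09, or 0.13 with an estimated correlation). These included the regulator Ppara (−3.62 ± 0.60, adjusted p = 3.1e-05) and the dehydrogenase gene Acadm (−2.51 ± 0.20).

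Several stress programs were raised at 24 h. Immediate early genes rose in 16 of 20 cases (16 adjusted over the list alone, median 1.75, camera adjusted p = 2.3e-06, or 0.21 with an estimated correlation). Complement and acute phase genes gave 12 rises and 1 fall among 18 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00044, or 0.25 with an estimated correlation), with the serum amyloid gene Saa3 up by 6.63 ± 0.97. The neutrophil chemokine Cxcl1 rose by 6.58 ± 0.73. The largest rises among genes of at least moderate abundance included the peptide genes Grp (10.23 ± 1.45, adjusted p = 9.0e-06, or 11.46 without Control library 4) and Vgf (7.26 ± 1.03) and the epithelial barrier gene Sprr2f (8.42 ± 0.79, adjusted p = 1.3e-08). Of 15 connexin and nanotube genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.94). The vascular connexins Gja4 (2.42 ± 0.30, adjusted p = 8.0e-07) and Gja5 (2.37 ± 0.46, adjusted p = 0.00022) rose and the epithelial connexin Gjb2 fell (−2.68 ± 0.44, adjusted p = 3.2e-05). In all, 6986 genes differed from Control, 3627 upward and 3359 downward, and 11567 with only these groups fitted. The 24 h libraries and Control stood in different joined blocks. These values carry that difference in full.

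At 48 and 72 h, S1 and S2 genes and nuclear genes of oxidative phosphorylation were lower than in Control. Mitochondrial ribosomal RNA took 1.78% to 2.56% of the counts at 48 h and 1.75% to 1.82% at 72 h, against 0.151% to 0.177% in Control. The same share thus moved with these changes. All 18 S1 and S2 genes fell at 48 h (18 adjusted over the list alone, median −3.90, camera adjusted p = 9.4e-10, or 0.25 with an estimated correlation). At 72 h all 18 were lower (18 adjusted over the list alone, median −4.61, camera adjusted p = 2.0e-08, or 0.28 with an estimated correlation). Slc34a1 stood at 515 ± 272 CPM at 48 h and 209 ± 32.7 CPM at 72 h, against 5462 ± 618 CPM in Control (n = 4 in each group, −4.71 ± 0.38, adjusted p = 6.6e-10 at 72 h). S3 genes fell in 14 of 14 cases at 48 h (14 adjusted over the list alone, median −3.21, camera adjusted p = 1.1e-08, or 0.23 with an estimated correlation). Oxidative phosphorylation genes fell in 41 of 52 cases at 48 h, with 2 rises (43 and 2 adjusted over the list alone, median −0.84, camera adjusted p = 3.3e-10, or 0.25 with an estimated correlation). At 72 h, 45 fell and 1 rose (45 and 1 adjusted over the list alone, median −0.71, camera adjusted p = 1.4e-10, or 0.28 with an estimated correlation). The ATP synthase gene Atp5a1 (−2.28 ± 0.12, adjusted p = 5.9e-13) and Sdha (−2.62 ± 0.17, adjusted p = 2.5e-11) were among those lower at 48 h. Fatty acid oxidation genes fell in 23 of 26 cases at 48 h (24 adjusted over the list alone, median −1.80, camera adjusted p = 5.0e-09, or 0.23 with an estimated correlation). Ppargc1a reached 18.2 ± 8.84 CPM at 48 h (−2.06 ± 0.24, adjusted p = 1.7e-07) and 14.2 ± 3.31 CPM at 72 h (−2.42 ± 0.25, adjusted p = 2.0e-08). Its homologue Ppargc1b fell at 48 h (−3.09 ± 0.49), while the biogenesis list went both ways, with 4 rises and 7 falls (4 and 7 adjusted over the list alone, camera adjusted p = 0.67).

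Injury genes were above Control in 17 of 18 cases at 48 h (17 adjusted over the list alone, median 2.51, camera adjusted p = 1.5e-08, or 0.25 with an estimated correlation). At 72 h 17 of them were (17 adjusted over the list alone, median 2.26, camera adjusted p = 6.1e-08, or 0.28 with an estimated correlation). Krt20 stood at 33.0 ± 14.5 CPM at 72 h (1.79 ± 0.56, adjusted p = 0.0090) and Timp1 was up by 5.03 ± 0.46. Cell cycle genes rose in 20 of 24 cases at 48 h (21 adjusted over the list alone, median 2.21, camera adjusted p = 2.9e-05, or 0.46 with an estimated correlation), including the mitotic regulator Foxm1 (3.24 ± 0.36). At 72 h 14 rose (15 adjusted over the list alone, median 1.56, camera adjusted p = 0.021, or 0.69 with an estimated correlation). The mitophagy receptor gene Bnip3 fell at 48 h (−2.14 ± 0.25, adjusted p = 2.1e-07). Among 17 genes of mitochondrial dynamics there were 10 falls and 1 rise (10 and 3 adjusted over the list alone, camera adjusted p = 0.022, or 0.23 with an estimated correlation). Cytokine and chemokine genes rose in 9 of 18 cases at 48 h (9 adjusted over the list alone, median 2.67, camera adjusted p = 0.034, or 0.41 with an estimated correlation). The chemokine Ccl20, which attracts immune cells through CCR6, went from 0.274 ± 0.206 CPM in Control to 1829 ± 202 CPM at 48 h (mean ± SD, n = 4, 12.65 ± 0.65, adjusted p = 7.4e-13). Ccl7, a monocyte attractant, went from 0.307 ± 0.132 to 1528 ± 548 CPM (12.23 ± 0.38, adjusted p = 6.3e-16). These chemokines carry a limit. Another chemokine, Ccl2, was held under its name in copies that were equal in Control and at 6 and 24 h but held 13476, 17121, 14755 and 11734 counts against 50, 28, 50 and 5 at 48 h. A difference confined to injured columns cannot be checked from Control counts. Cep85 rose from 129.7 ± 9.56 CPM in Control to 122634 ± 19316 CPM at 72 h (9.88 ± 0.51, adjusted p = 5.3e-13). Genes without a count in a group included the anion exchanger gene Slc4a1, at least 311-fold lower at 72 h, and the pyruvate kinase gene Pklr, at least 216-fold lower, against a floor of 3 counts over the 4 libraries.

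At 48 h 8948 genes differed from Control (4487 upward, 4461 downward) and at 72 h 9373 (4448 upward, 4925 downward). Scaling by DESeq2's size factors moved the median of all genes by 0.1035 at 48 h and by 0.1308 at 72 h on the log2 scale, so smaller changes at those times depend on the scaling. Both groups lay in another joined block than Control.

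Between 6 and 24 h, genes of mitosis, matrix and tubular function fell. Over this interval, 21 of 24 cell cycle genes fell (23 adjusted over the list alone, median −2.70, camera adjusted p = 2.7e-10, or 0.25 with an estimated correlation). Examples were the mitotic activator Cdc20 (−4.16 ± 0.49, adjusted p = 1.1e-06) and the spindle gene Kif20a (−4.27 ± 0.76). Fibroblast and matrix genes fell in 9 of 16 cases (9 adjusted over the list alone, camera adjusted p = 1.8e-05, or 0.24 with an estimated correlation), Col1a1 by 2.78 ± 0.20. S1 and S2 genes fell in 14 of 18 cases (15 adjusted over the list alone, camera adjusted p = 6.1e-10, or 0.24 with an estimated correlation). Ppargc1a fell (−2.04 ± 0.24, adjusted p = 8.6e-07), and Umod did too (−2.54 ± 0.21, adjusted p = 5.1e-09). Krt20 (adjusted p = 0.87) and Sox9 (adjusted p = 0.13) did not pass. These 4800 genes, 2484 upward and 2316 downward, were compared across the joined blocks, and 8302 were called with only these groups fitted.

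From 24 to 48 h, within one block, oxidative phosphorylation genes fell in 35 of 52 cases (38 adjusted over the list alone, median −0.57, camera adjusted p = 5.7e-14, or 0.18 with an estimated correlation), the cytochrome oxidase gene Cox6a1 at −1.33 ± 0.12, adjusted p = 2.9e-07. NRF2 targets fell in 11 of 20 cases (12 adjusted over the list alone, camera adjusted p = 0.00027, or 0.26 with an estimated correlation), Hmox1 at −1.42 ± 0.38, adjusted p = 0.0098, and Krt20 fell (−1.98 ± 0.53, adjusted p = 0.0098). Acute phase genes gave 10 falls and 1 rise (12 and 1 adjusted over the list alone, camera adjusted p = 1.2e-05, or 0.18 with an estimated correlation), with the fibrinogen gene Fgb at −4.32 ± 0.77, adjusted p = 0.00033, or −6.34 without IRI 48 h library 1. Their median of −2.93 became −2.69 with genes lacking counts held at their bound. Cell cycle genes rose again in 12 of 24 cases (12 adjusted over the list alone, camera adjusted p = 0.00016, or 0.40 with an estimated correlation). Slc12a1 and Egf of the thick ascending limb rose (2.35 ± 0.30 and 1.65 ± 0.28). Their list had 8 rises and 1 fall (8 and 1 adjusted over the list alone, camera adjusted p = 0.0027, or 0.22 with an estimated correlation). Ppargc1a did not pass (−0.37 ± 0.24, adjusted p = 0.30), although it fell by 0.75 without IRI 48 h library 2 (adjusted p = 0.010). Of 3511 genes called, 1499 rose and 2012 fell. The share of rises was 42.7%, and 54.4% with DESeq2's size factors, which moved the median of all genes by 0.10.

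From 48 to 72 h 944 genes were called (340 upward, 604 downward). This count depends on the fit, with 24 genes (20 upward) when only these groups were fitted and 2001 by DESeq2. The S1 glucose transporter gene Slc5a2 fell further (−3.97 ± 0.56, adjusted p = 0.00071). Interferon response genes fell in 5 of 20 cases (6 adjusted over the list alone, median −0.68, camera adjusted p = 0.0029, or 0.49 with an estimated correlation), including Isg15 (−1.40 ± 0.36, adjusted p = 0.026). Of 24 cell cycle genes, 3 fell (6 adjusted over the list alone, camera adjusted p = 0.0041, or 0.91 with an estimated correlation), Mcm2 at −0.89 ± 0.20, adjusted p = 0.017. Genes of adrenal tissue, which lies on the kidney's upper pole, rose in 5 of 8 cases (8 adjusted over the list alone, camera adjusted p = 0.0073, or 0.91 with an estimated correlation). Their median of 7.55 became 5.24 at the bound, and Cyp21a1, the adrenal steroid hydroxylase gene, was at least 1096-fold higher than the floor of 3 counts over the 48 h group. Libraries 2 and 4 carried this rise, as the mean log2 of the list ranged over 5.36 within the 72 h group.

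**Figure D2:**
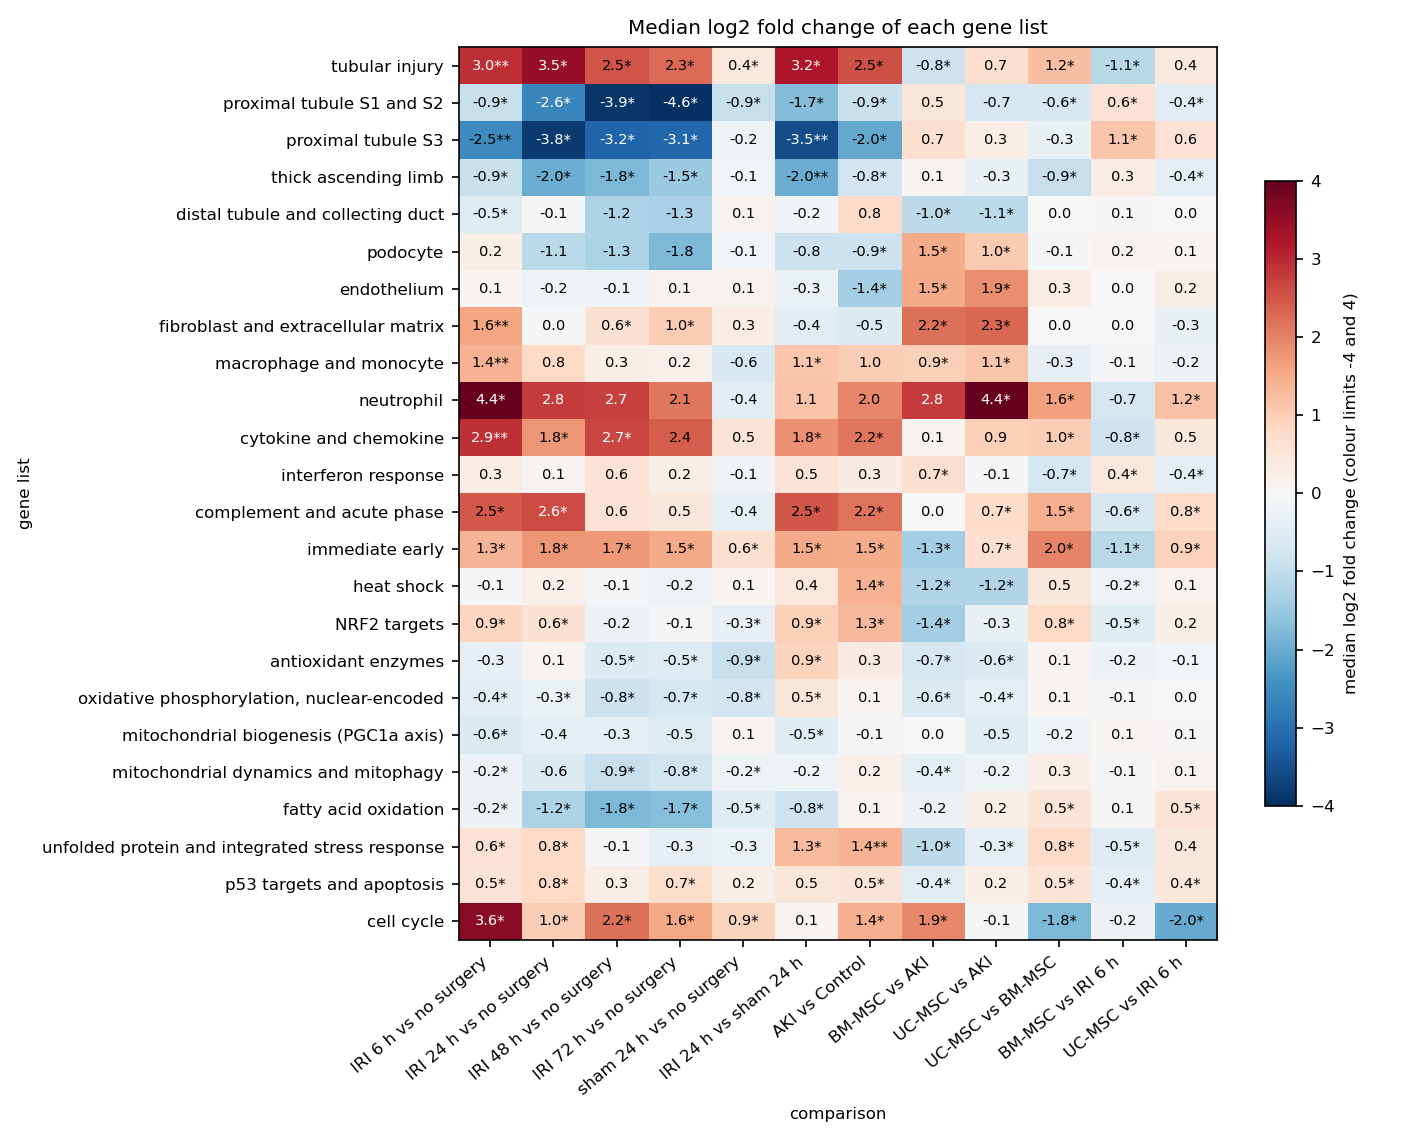
Median log2 fold change of 24 gene lists (vertical axis) in 12 comparisons (horizontal axis), with colours limited to −4 and 4. One star marks a camera adjusted p under 0.05 at the preset correlation and a double star one that also holds with an estimated correlation. The S1 and S2 list went from −0.93 at 6 h to −4.61 at 72 h.

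Surgery without ischaemia raised part of the tubular injury list, without a call for Havcr1 or Lcn2. It lowered genes of mitochondrial respiration, antioxidant enzymes and the proximal tubule's S1 and S2 segments. Havcr1, the kidney injury molecule gene, was at 0.453 ± 0.315 CPM without surgery and 0.457 ± 0.573 CPM 24 h after sham surgery (mean ± SD, n = 4 in each group, adjusted p = 1.0). The injury gene Lcn2 did not pass either (0.58 ± 0.32, adjusted p = 0.23), nor did Gja1 (0.39 ± 0.33, adjusted p = 0.46) or Krt20 (0.97 ± 0.65, adjusted p = 0.35). Of the whole tubular injury list, 7 of 19 genes rose and 0 fell (7 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 0.030, or 0.49 with an estimated correlation), Cdkn1a by 1.23 ± 0.27, adjusted p = 0.0032 and the keratin gene Krt18 by 0.70 ± 0.11, adjusted p = 0.00033. Of 52 oxidative phosphorylation genes, 51 fell (52 adjusted over the list alone, median −0.76, camera adjusted p = 3.3e-36, or 0.30 with an estimated correlation), such as Cox5a (−1.39 ± 0.19) and Ndufa4 (−1.29 ± 0.11). Over the same comparison, mitochondrial names went from 33.3 ± 2.79% to 48.6 ± 3.46% of the counts, and mitochondrial ribosomal RNA from between 0.273% and 0.488% to between 0.633% and 0.753%. All 17 antioxidant enzyme genes fell (17 adjusted over the list alone, median −0.91, camera adjusted p = 1.4e-17, or 0.30 with an estimated correlation). The mitochondrial superoxide dismutase gene Sod2 went from 287 ± 13.98 to 158 ± 27.0 CPM (−0.86 ± 0.12, adjusted p = 6.2e-05) and the peroxidase gene Gpx1 fell (−1.75 ± 0.17). Transcripts encoded by mitochondrial DNA went the other way, with 8 rises among 13 (12 adjusted over the list alone, median 0.60, camera adjusted p = 2.5e-07, or 0.49 with an estimated correlation), mt-Co1 by 0.69 ± 0.13, adjusted p = 0.00086. S1 and S2 genes fell in 15 of 18 cases (16 adjusted over the list alone, median −0.91, camera adjusted p = 2.7e-14, or 0.31 with an estimated correlation), including Slc34a1 (−0.94 ± 0.14, adjusted p = 0.00011). Ppargc1a did not pass (−0.23 ± 0.15, adjusted p = 0.32), though it did without sham library 4 (−0.40, adjusted p = 0.037). Tfam fell (−0.59 ± 0.17, adjusted p = 0.017), a call that ended without unoperated library 2 (−0.52, adjusted p = 0.072).

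Proliferation genes rose after sham surgery in 7 of 25 cases (8 adjusted over the list alone, median 0.89, camera adjusted p = 0.00014, or 0.30 with an estimated correlation), Mki67 from 5.27 ± 0.792 to 17.2 ± 5.03 CPM (1.70 ± 0.22, adjusted p = 4.3e-05). The lipid hydroxylase gene Cyp4a14, a target of PPARa, rose (2.75 ± 0.18, adjusted p = 1.7e-07), and androgen-dependent Cyp2a4 fell from 217 ± 31.9 to 6.79 ± 5.84 CPM (−4.99 ± 0.47, adjusted p = 2.5e-06, or −5.68 without sham library 3). The serum amyloid gene Saa1 was at least 41.0-fold higher than the floor of 3 counts over the unoperated group. Of 17781 genes tested, 3703 differed, 1369 upward and 2334 downward, with 323 and 512 at 2-fold or more. The treatment tag of the sham-operated samples reads IRI, while their source names and titles give surgery without it, and the latter were followed.

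The change at 24 h after IRI minus that after sham surgery was taken, each against its own unoperated controls. Tubular injury and transport genes differed widely. Injury genes were higher in 17 of 18 cases (17 adjusted over the list alone, median 3.25, camera adjusted p = 1.1e-11, or 0.13 with an estimated correlation), Krt20 by 3.59 ± 0.85, adjusted p = 0.0018 and the TWEAK receptor gene Tnfrsf12a by 4.33 ± 0.39. S3 genes were lower in 13 of 14 cases (13 adjusted over the list alone, median −3.54, camera adjusted p = 8.2e-17, or 0.023 with an estimated correlation). S1 and S2 genes were lower in 14 of 18 (14 adjusted over the list alone, median −1.74, camera adjusted p = 1.1e-11, or 0.18 with an estimated correlation). Egf (−6.42 ± 0.36, adjusted p = 1.9e-13) and Umod (−2.09 ± 0.26, adjusted p = 2.2e-07) were lower. Ppargc1a was lower as well (−1.44 ± 0.30, adjusted p = 0.00042), while Tfam did not pass (−0.44 ± 0.34, adjusted p = 0.39). Of 52 oxidative phosphorylation genes, 26 were higher and 3 lower (28 and 5 adjusted over the list alone, median 0.47, camera adjusted p = 3.6e-06, or 0.36 with an estimated correlation), and the same list had fallen after sham surgery. Fatty acid oxidation genes were lower in 13 of 26 cases and higher in 1 (14 and 1 adjusted over the list alone, median −0.83, camera adjusted p = 2.0e-06, or 0.20 with an estimated correlation), with Cyp4a14 at −4.10 ± 0.45, adjusted p = 3.1e-08. Hmox1 (3.74 ± 0.49, adjusted p = 6.7e-07) and Gpx1 (3.37 ± 0.29) were higher, as were Gja4 (2.32 ± 0.40, adjusted p = 3.6e-05) and Gja5 (1.65 ± 0.56, adjusted p = 0.029). Of 19616 genes, 4774 differed, 2707 upward and 2067 downward, and 8340 with only these groups fitted. The arms differed in depth and unoperated baseline. Umod stood at 129 to 178.5 CPM in sham controls and 2294.5 to 2706 CPM in Control. The joined block of the 24 h libraries is also part of this difference.

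In the therapy arm, untreated injury (AKI, labelled as taken 6 h after reperfusion) had higher stress response and injury genes and lower genes of the endothelium than Control. Mitochondrial ribosomal RNA took 0.848% to 1.87% of the counts in AKI, against 0.153% to 0.18% in Control. It took 0.134% to 0.237% in BM-MSC, 0.216% to 0.398% in UC-MSC and 0.205% to 0.444% in IRI 6 h. This share thus differed along with the joined block, and whether it reflects RNA preparation or the injury was not tested. Injury genes rose in 16 of 18 cases (16 adjusted over the list alone, median 2.54, camera adjusted p = 5.2e-10, or 0.24 with an estimated correlation). Krt20 went from 8.81 ± 4.81 to 146 ± 48.4 CPM (mean ± SD, n = 4 in each group, 4.05 ± 0.50, adjusted p = 3.8e-05) and Sox9 from 1.38 ± 0.340 to 50.2 ± 32.3 CPM (5.18 ± 0.54, adjusted p = 9.6e-06). NRF2 targets gave 15 rises and 1 fall among 20 (15 and 1 adjusted over the list alone, median 1.31, camera adjusted p = 1.4e-05, or 0.34 with an estimated correlation). Hmox1 was at 33.3 ± 3.60 CPM in Control and 739 ± 282 CPM in AKI (4.47 ± 0.35, adjusted p = 2.1e-06). Unfolded protein and integrated stress response genes rose in 13 of 17 cases (14 adjusted over the list alone, median 1.39, camera adjusted p = 2.0e-07, or 0.030 with an estimated correlation), including the pseudokinase gene Trib3 (4.99 ± 0.56, adjusted p = 1.6e-05) and the asparagine synthetase gene Asns (3.54 ± 0.44). Heat shock genes rose in 10 of 14 cases (12 adjusted over the list alone, median 1.39, camera adjusted p = 3.4e-05, or 0.24 with an estimated correlation), Hsp90aa1 by 2.29 ± 0.20. Hspa1a also rose (3.53 ± 1.04, adjusted p = 0.015), but by 0.04 without AKI library 1 (adjusted p = 0.95).

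Vessel genes fell in AKI in 8 of 12 cases (9 adjusted over the list alone, median −1.37, camera adjusted p = 2.0e-07, or 0.34 with an estimated correlation). They included the fenestral diaphragm gene Plvap (−3.05 ± 0.30, adjusted p = 7.2e-06) and the TGF-beta coreceptor gene Eng (−2.19 ± 0.20, adjusted p = 3.7e-06). S3 genes fell in 11 of 14 cases (12 adjusted over the list alone, camera adjusted p = 2.0e-06, or 0.34 with an estimated correlation), Cyp7b1 at −4.54 ± 0.73, adjusted p = 0.00026. Thick ascending limb genes fell in 7 of 14 (7, with 1 rise, adjusted over the list alone, camera adjusted p = 0.0062, or 0.36 with an estimated correlation). Umod went from 2336 ± 145 to 271 ± 194 CPM (−3.11 ± 0.84, adjusted p = 0.0095). Ppargc1a, at 70.1 ± 1.66 CPM in Control and 49.1 ± 17.6 CPM in AKI, did not pass (−0.51 ± 0.23, adjusted p = 0.091), and passed without AKI library 1 (−0.80, adjusted p = 0.0044). Without that library, Cyp7b1 stood at −5.29 and Umod at −3.76. Of 18 biogenesis genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.59), with Pprc1 (1.72 ± 0.20) and Ssbp1 (1.09 ± 0.19) upward and the RNA polymerase gene Polrmt downward (−0.97 ± 0.13). Among 16 connexin and nanotube genes, Panx1 (1.86 ± 0.57, adjusted p = 0.020), the mitochondrial transport gene Rhot2 (0.73 ± 0.18) and Rala (0.65 ± 0.12) rose (3 adjusted over the list alone, camera adjusted p = 0.89). In total, 5821 of 16623 genes differed from Control, 3317 upward and 2504 downward. AKI stood alone in its joined block. Its library 1 lay apart from the other 3, and 8167 genes were called without it.

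Kidneys given BM-MSCs, read against AKI, had more transcripts of vessels, matrix and dividing cells and fewer of the stress responses. Endothelial genes were higher in 8 of 12 cases (10 adjusted over the list alone, median 1.503, camera adjusted p = 5.0e-07, or 0.34 with an estimated correlation), Plvap by 3.08 ± 0.30, adjusted p = 7.8e-06 and Eng by 2.11 ± 0.20. Fibroblast and matrix genes gave 12 rises and 2 falls among 16 (13 and 3 adjusted over the list alone, median 2.20, camera adjusted p = 5.9e-06, or 0.41 with an estimated correlation), with Col3a1 at 4.03 ± 0.42, adjusted p = 1.1e-05. The calcification inhibitor gene Mgp went from 17.8 ± 14.2 to 452 ± 107 CPM (mean ± SD, n = 4 in each group, 4.67 ± 0.47, adjusted p = 8.8e-06, or 5.37 without AKI library 1). Cell cycle genes rose in 13 of 24 cases (13 adjusted over the list alone, median 1.92, camera adjusted p = 4.3e-05, or 0.60 with an estimated correlation), Ccnb1 by 4.34 ± 0.72, adjusted p = 0.00040, or by 5.23 without AKI library 2. NRF2 targets fell in 12 of 20 cases (16 adjusted over the list alone, median −1.37, camera adjusted p = 5.9e-06, or 0.34 with an estimated correlation), and Hmox1 went from 739 ± 282 to 72.6 ± 34.8 CPM (−3.35 ± 0.33, adjusted p = 7.8e-06). Stress response genes fell in 11 of 17 cases (11, with 1 rise, adjusted over the list alone, median −1.04, camera adjusted p = 5.9e-06, or 0.088 with an estimated correlation), for example Trib3 (−3.74 ± 0.51, adjusted p = 9.7e-05) and the CHOP gene Ddit3 (−2.79 ± 0.23). Heat shock genes fell in 10 of 14 cases (13 adjusted over the list alone, median −1.22, camera adjusted p = 5.1e-06, or 0.30 with an estimated correlation), Hsp90aa1 at −2.22 ± 0.20.

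Neutrophil genes rose with BM-MSCs in 5 of 9 cases (6 adjusted over the list alone, median 2.81, camera adjusted p = 0.15). The gelatinase gene Mmp9 rose by 5.33 ± 1.14, adjusted p = 0.0023, or 2.86 without BM-MSC library 4, and S100a8 by 3.27 ± 0.99, adjusted p = 0.019, a call that ended without BM-MSC library 4 (0.91, adjusted p = 0.34) and without AKI library 3 or 4 (3.18 and 2.93). Injury genes went both ways, 8 down and 1 up of 18 (8 and 1 adjusted over the list alone, median −0.83, camera adjusted p = 0.0095, or 0.58 with an estimated correlation). Sox9 fell (−2.73 ± 0.46, adjusted p = 0.00043) and Umod rose to 2217 ± 577 CPM (3.03 ± 0.84, adjusted p = 0.011, or 3.66 without AKI library 1). Krt20 fell to 55.7 ± 37.7 CPM (−1.39 ± 0.45, adjusted p = 0.025), a call that ended when AKI library 2 or 3 or BM-MSC library 1, 2 or 3 was left out, with values of −1.24, −1.31, −1.38, −1.13 and −1.22. Oxidative phosphorylation genes were lower in 22 of 52 cases (26 adjusted over the list alone, median −0.59, camera adjusted p = 2.3e-07, or 0.60 with an estimated correlation), Uqcrb at −1.43 ± 0.19. Ppargc1a did not pass (0.25 ± 0.23, adjusted p = 0.43), at 58.2 ± 12.4 CPM, and passed without AKI library 1 (0.51, adjusted p = 0.049). Tfam fell from 88.5 ± 14.8 to 56.8 ± 4.67 CPM (−0.64 ± 0.15, adjusted p = 0.0036), within a biogenesis list of 2 rises and 5 falls (2 and 5 adjusted over the list alone, camera adjusted p = 0.29). Of 16 connexin and nanotube genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.92), with Rhot2 (−1.14 ± 0.18, adjusted p = 0.00027) and Gjb2 (−1.07 ± 0.28) lower and the junction scaffold gene Tjp1 higher (1.01 ± 0.33). Genes of brown and white fat around the kidney fell in all 8 cases (8 adjusted over the list alone, camera adjusted p = 5.0e-07, or 0.32 with an estimated correlation), Fabp4 at −2.71 ± 0.37. Of 5552 genes called, 2715 were higher and 2837 lower, with 8111 called without AKI library 1 and 3638 with only these groups fitted. The joined block of AKI and the unlabelled sampling time of the MSC groups are part of this comparison.

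UC-MSC kidneys, read against AKI, also had more transcripts of vessels, matrix and neutrophils. All 12 endothelial genes were higher (12 adjusted over the list alone, median 1.85, camera adjusted p = 2.8e-07, or 0.50 with an estimated correlation), Plvap by 2.94 ± 0.30, adjusted p = 7.4e-06. So were 13 of 16 matrix genes (13 adjusted over the list alone, median 2.29, camera adjusted p = 9.2e-06, or 0.63 with an estimated correlation), the stromal receptor gene Pdgfra by 3.10 ± 0.38. All 9 neutrophil genes rose (9 adjusted over the list alone, median 4.44, camera adjusted p = 0.0018, or 0.63 with an estimated correlation). S100a8 was at 3.23 ± 2.31 CPM in AKI and 96.3 ± 57.8 CPM with UC-MSCs (mean ± SD, n = 4 in each group, 4.91 ± 1.05, adjusted p = 0.0019). Complement and acute phase genes rose in 8 of 18 cases (8 adjusted over the list alone, camera adjusted p = 0.020, or 0.63 with an estimated correlation), Saa3 by 4.21 ± 0.68. Krt20 rose from 146 ± 48.4 to 903 ± 273 CPM (2.62 ± 0.47, adjusted p = 0.00046), Timp1 by 2.45 ± 0.56 and the cell cycle inhibitor gene Cdkn1a to 526 ± 444 CPM (2.39 ± 0.47, adjusted p = 0.0010, or 1.61 without UC-MSC library 4). The injury list gave 9 rises among 18 (9 adjusted over the list alone, median 0.66, camera adjusted p = 0.061). Hmox1 (adjusted p = 0.57), Umod (adjusted p = 0.92) and Sox9 (adjusted p = 0.69) did not pass.

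Ppargc1a was lower with UC-MSCs than in AKI, at 26.4 ± 6.62 CPM (−0.89 ± 0.23, adjusted p = 0.0064), and so were Tfam (−0.75 ± 0.15, adjusted p = 0.00094) and the mitochondrial transcription gene Tfb1m (−1.74 ± 0.30). The biogenesis list had 1 rise and 8 falls among 18 (2 and 8 adjusted over the list alone, median −0.48, camera adjusted p = 0.057). Oxidative phosphorylation genes were lower in 20 of 52 cases (19 adjusted over the list alone, median −0.40, camera adjusted p = 9.0e-06, or 0.71 with an estimated correlation). Stress response genes gave 7 falls and 1 rise (8 and 1 adjusted over the list alone, camera adjusted p = 0.020, or 0.50 with an estimated correlation), with Trib3 at −1.77 ± 0.47, adjusted p = 0.0074. Of 16 connexin and nanotube genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.75). Gja4 (1.24 ± 0.42, adjusted p = 0.029), Gjc1 (1.68 ± 0.61, adjusted p = 0.036) and the nanotube gene Tnfaip2 (1.18 ± 0.34) rose and Rhot2 fell (−1.31 ± 0.18, adjusted p = 6.6e-05). In total 6729 genes differed, 3378 upward and 3351 downward, with 9021 called without AKI library 1 and 3535 with only these groups fitted.

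The MSC sources themselves differed within one joined block, so that this comparison does not involve AKI. UC-MSC kidneys had higher injury, immediate early and hypoxia transcripts and fewer of dividing cells than BM-MSC kidneys. Injury genes were higher in 7 of 18 cases (11 adjusted over the list alone, median 1.19, camera adjusted p = 1.4e-06, or 0.24 with an estimated correlation). Krt20 was higher by 4.02 ± 0.50, adjusted p = 0.00028, Sox9 by 2.96 ± 0.47, adjusted p = 0.0011 and Cdkn1a by 3.48 ± 0.49, adjusted p = 0.00059, or by 2.70 without UC-MSC library 4. Immediate early genes were higher in 14 of 21 cases (18 adjusted over the list alone, median 1.97, camera adjusted p = 3.0e-10, or 0.24 with an estimated correlation), among them Fosl1 (3.60 ± 0.52, adjusted p = 0.00066). Hypoxia genes were higher in 7 of 15 cases (10, with 1 lower, adjusted over the list alone, median 0.79, camera adjusted p = 2.1e-05, or 0.011 with an estimated correlation), including adrenomedullin, Adm (2.25 ± 0.27, adjusted p = 0.00022). NRF2 targets were higher in 7 of 20 cases (8 adjusted over the list alone, camera adjusted p = 4.0e-05, or 0.24 with an estimated correlation), Hmox1 by 3.12 ± 0.33, adjusted p = 0.00012. Cell cycle genes were lower in 13 of 24 cases (19 adjusted over the list alone, median −1.81, camera adjusted p = 1.1e-09, or 0.34 with an estimated correlation), with Ccna2 at −2.40 ± 0.65, adjusted p = 0.017. Neutrophil genes were higher in 3 of 9 cases (3 adjusted over the list alone, median 1.63, camera adjusted p = 0.00018, or 0.34 with an estimated correlation), the resistin-like gene Retnlg by 3.82 ± 1.00, adjusted p = 0.015, while S100a8 did not pass (1.63 ± 0.90, adjusted p = 0.21, or 3.97 with adjusted p = 0.0024 without BM-MSC library 4). S1 and S2 genes were lower in 7 of 18 cases (8 adjusted over the list alone, median −0.64, camera adjusted p = 9.2e-05, or 0.34 with an estimated correlation), Lrp2 at −1.62 ± 0.37, adjusted p = 0.0067.

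Of 18 biogenesis genes, 4 were lower with UC-MSCs than with BM-MSCs. These were Ppargc1a (−1.14 ± 0.23, adjusted p = 0.0039), the receptor genes Esrra (−0.77 ± 0.18, adjusted p = 0.0082) and Esrrg (−0.59 ± 0.18, adjusted p = 0.032), and Tfb1m (−1.06 ± 0.29, adjusted p = 0.019). The rest did not pass (5 lower adjusted over the list alone, camera adjusted p = 0.20). Gjb2 (1.12 ± 0.28, adjusted p = 0.012) and Rala (0.38 ± 0.12, adjusted p = 0.037) were higher among 16 connexin and nanotube genes (1 adjusted over the list alone, camera adjusted p = 0.51). The immunophilin gene Fkbp1a went from 215 ± 35.2 to 26.1 ± 14.6 CPM (mean ± SD, n = 4 in each group, −3.04 ± 0.31, adjusted p = 0.00010). Adrenal steroid genes were higher in all 9 cases (9 adjusted over the list alone, median 5.64, camera adjusted p = 0.0015, or 0.46 with an estimated correlation), the aldosterone synthase gene Cyp11b2 by 8.57 ± 2.04, adjusted p = 0.0087, or 9.37 without BM-MSC library 1 and 6.76 without UC-MSC library 3. Of 3402 genes called, 1668 were higher and 1734 lower with UC-MSCs. Without UC-MSC library 3 the count was 1947, and without BM-MSC library 1, 2 or 3 it was 2084, 2214 and 2257.

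Against uninjured Control in the same block, BM-MSC kidneys had more transcripts of dividing cells, injury, matrix, neutrophils and macrophages, and fewer of the S3 segment. Cell cycle genes were higher in 23 of 24 cases (24 adjusted over the list alone, median 3.50, camera adjusted p = 2.4e-19, or 0.29 with an estimated correlation), Bub1 by 4.35 ± 0.92, adjusted p = 0.0089. Injury genes were higher in 13 of 18 cases (18 adjusted over the list alone, median 1.77, camera adjusted p = 4.0e-12, or 0.29 with an estimated correlation), Krt20 by 2.66 ± 0.48, adjusted p = 0.0037 and Sox9 by 2.44 ± 0.50, adjusted p = 0.0077. Matrix genes were higher in 9 of 16 cases (12 adjusted over the list alone, camera adjusted p = 2.7e-08, or 0.29 with an estimated correlation), Col3a1 by 2.93 ± 0.40, adjusted p = 0.0011. Neutrophil genes were higher in 6 of 9 cases (7 adjusted over the list alone, median 4.34, camera adjusted p = 0.045, or 0.64 with an estimated correlation) and macrophage and monocyte genes in 11 of 17 (14 adjusted over the list alone, median 1.55, camera adjusted p = 4.1e-07, or 0.29 with an estimated correlation). S100a8 was higher by 5.34 ± 1.15, adjusted p = 0.0096, S100a9 by 4.77 ± 1.04, adjusted p = 0.010 and Chil3 by 5.06 ± 0.99, adjusted p = 0.0061. Without BM-MSC library 4 these stood at 2.96, 2.43 and 3.36, and the call of S100a9 ended (adjusted p = 0.051). S3 genes were lower in 6 of 14 cases (10 adjusted over the list alone, camera adjusted p = 6.7e-08, or 0.29 with an estimated correlation), Cyp4b1 at −1.96 ± 0.39, adjusted p = 0.0061. No S1 and S2 gene passed edgeR's test, although the list lay lower (0 adjusted over the list alone, median −0.48, camera adjusted p = 0.0024, or 0.47 with an estimated correlation). Ppargc1a did not pass (adjusted p = 0.51). In all 1483 genes differed, 1090 upward and 393 downward. Without BM-MSC library 4 the count was 582, and without Control library 1, 2, 3 or 4 it was 766, 656, 656 and 753. Fitting only these groups gave 4970 genes, 54.7% of them upward in place of 73.5%, and DESeq2 gave 2303.

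UC-MSC kidneys differed from Control in 6172 genes, of which 3396 were higher and 2776 lower. All 18 injury genes were higher (18 adjusted over the list alone, median 3.35, camera adjusted p = 1.6e-12, or 0.12 with an estimated correlation), Krt20 by 6.68 ± 0.57, adjusted p = 3.4e-06 and Cdkn1a by 4.92 ± 0.53, adjusted p = 1.5e-05, or by 4.14 without UC-MSC library 4. Neutrophil genes were higher in 8 of 9 cases (8 adjusted over the list alone, camera adjusted p = 0.00081, or 0.38 with an estimated correlation). Cytokine and chemokine genes were higher in 15 of 19 (16 adjusted over the list alone, camera adjusted p = 5.0e-05, or 0.30 with an estimated correlation). The granule gene Ngp was at least 334-fold higher than a floor of 3 counts over Control. S1 and S2 genes were lower in 13 of 18 cases (14 adjusted over the list alone, median −1.57, camera adjusted p = 4.7e-07, or 0.23 with an estimated correlation), Slc34a1 at −1.86 ± 0.48, adjusted p = 0.0066 and Lrp2 at −1.83 ± 0.37, adjusted p = 0.0014. Ppargc1a (−1.41 ± 0.23, adjusted p = 0.00034) and Esrra (−1.15 ± 0.18, adjusted p = 0.00022) were lower, in a biogenesis list of 8 falls and 2 rises (8 and 2 adjusted over the list alone, camera adjusted p = 0.0059, or 0.21 with an estimated correlation).

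**Figure D3:**
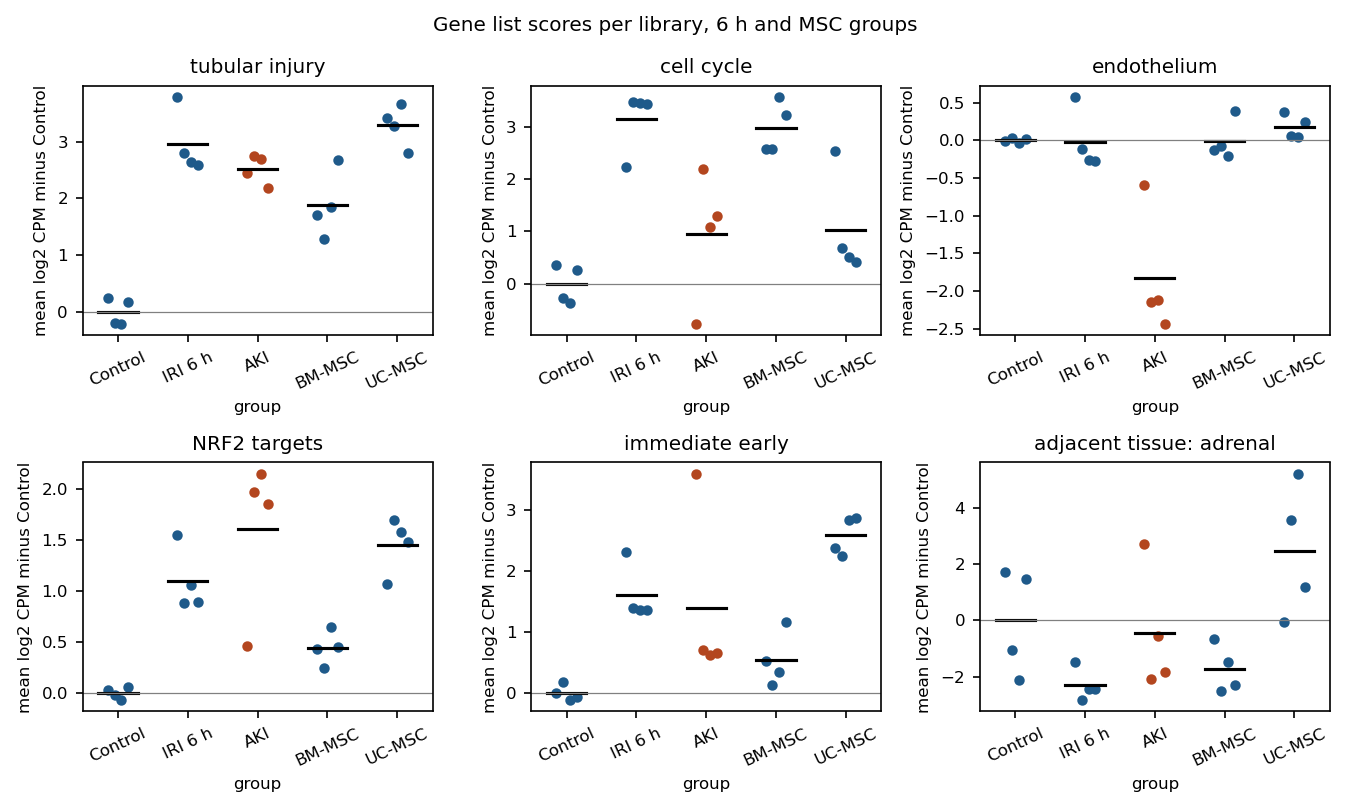
Mean log2 CPM of 6 gene lists in each library, minus the Control mean (vertical axis), for Control, IRI 6 h, AKI, BM-MSC and UC-MSC libraries (horizontal axis), with bars at the group mean. AKI, in orange, came from another joined block than Control, BM-MSC and UC-MSC, and IRI 6 h shared Control's block in the temporal arm. Median cell cycle change was 3.50 for BM-MSC and 1.42 for AKI, each against Control.

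Changes in AKI were frequently opposite in the MSC groups. Of 5821 genes changed in AKI, 3583 were called the opposite way with BM-MSCs and 33 the same way. The 3583 held 1997 genes raised then lowered (such as Hmox1, Sox9 and Trib3) and 1586 lowered then raised (such as Plvap, Eng and Umod). With UC-MSCs, 2783 genes were opposite (1448 and 1335 in these directions) and 307 the same way. The AKI libraries (IRI 6 h below) enter both comparisons with opposite sign. Groups simulated as unchanged from AKI gave on average 0.40 and 0.45 opposite genes. Covariances of log2 fold changes were −0.79 (BM-MSC) and −0.57 (UC-MSC), against −0.08 simulated. With AKI divided so that each comparison used its own 2 libraries, 1970 to 2060 genes were opposite for BM-MSC and 1580 to 1804 for UC-MSC. The simulation gave 6749 injury genes on average, so it may lack AKI's real spread. Neither it nor the division removes AKI's joined block. With IRI 6 h in place of AKI, 0 genes were opposite for BM-MSC, where no gene was called, and 476 for UC-MSC.

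A second untreated group taken at 6 h, the IRI 6 h libraries, shared the MSC groups' joined block, and it gave another picture of the same treatments. This comparison was chosen after the joined blocks were seen. Against IRI 6 h, edgeR's quasi-likelihood test called 0 of 16821 genes for BM-MSC, with 2700 genes at an unadjusted p under 0.05 and 215 called by DESeq2. Krt20 (−2.09 ± 0.57, adjusted p = 0.19), Sox9 (−2.04 ± 0.42, adjusted p = 0.14), Hmox1 (−1.66 ± 0.44, adjusted p = 0.18) and Ppargc1a (−0.71 ± 0.22, adjusted p = 0.20) all lay lower without passing. As a list, injury genes were lower (median −1.10, camera adjusted p = 1.4e-09, or 0.23 with an estimated correlation), with 12 lower adjusted over the list alone and 0 over all genes. Immediate early genes followed (median −1.10, 7 lower adjusted over the list alone, 0 over all genes, camera adjusted p = 1.1e-07, or 0.44 with an estimated correlation). For UC-MSC against IRI 6 h, 1954 genes were called, 877 higher and 1077 lower, or 499 to 3047 with single libraries left out. Cell cycle genes were lower in 17 of 24 cases (23 adjusted over the list alone, median −2.01, camera adjusted p = 1.8e-14, or 0.58 with an estimated correlation), Fkbp1a fell (−3.71 ± 0.31, adjusted p = 3.5e-06), and Ppargc1a was lower (−1.86 ± 0.23, adjusted p = 0.00086). Krt20 (1.93 ± 0.57, adjusted p = 0.035) and Hmox1 (1.45 ± 0.44, adjusted p = 0.039) were higher.

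The untreated injured groups at 6 h also differed from each other, in 5800 genes, 2832 higher and 2968 lower in AKI than in IRI 6 h. Vessel genes were lower in AKI in 9 of 12 cases (12 adjusted over the list alone, median −1.42, camera adjusted p = 9.7e-07, or 0.39 with an estimated correlation). Matrix genes were lower in 12 of 16 (12 adjusted over the list alone, median −1.90, camera adjusted p = 9.7e-07, or 0.39 with an estimated correlation). Cell cycle genes were lower in 13 of 24 (14 adjusted over the list alone, median −2.22, camera adjusted p = 9.0e-06, or 0.74 with an estimated correlation). Mgp (−4.63 ± 0.50, adjusted p = 3.0e-06), Ppargc1a (−0.97 ± 0.22, adjusted p = 0.0025) and Umod (−2.61 ± 0.76, adjusted p = 0.012) were lower. Hmox1 was higher (1.68 ± 0.44, adjusted p = 0.0065) and Krt20 did not pass (−0.69 ± 0.55, adjusted p = 0.35).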

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

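All tests of the cell cycle pattern, the tests of MSC treatment as the whole cause, of the MSC source for the adrenal genes, and the splits of the temporal arm and of comparisons with IRI 6 h were chosen after the results they concern had been seen. The other tests were fixed before. Single libraries lay far from the other 3 of their group in 17 of 176 groups of 4 examined, where chance gives about 1 in 20, or 8.8. The pattern therefore holds flags that chance alone would give.

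IRI 6 h library 1 stood above the others of its group in several injury genes. It held 619 CPM of Krt20 (others 97.3 to 126.5), 559 CPM of Hmox1 (108 to 143), 135 CPM of S100a8 (14.1 to 19.5), 382 CPM of Cdkn1a (73.5 to 95.9), 179 CPM of Nfe2l2 (119 to 124) and 29.96 CPM of Hspa1a (13.96 to 16.7). Its share of mitochondrial ribosomal RNA was 0.444%, against 0.205% to 0.216%. AKI library 1 held 1.87% mitochondrial ribosomal RNA (others 0.848% to 0.989%), 217 CPM of Nfe2l2 (135 to 142) and 815 CPM of the heat shock gene Hspa1a (12.8 to 25.9). AKI library 4 held 7.75 CPM of the macrophage gene Adgre1 (3.59 to 4.29). BM-MSC library 4 held 106 CPM of S100a8 (3.92 to 8.58) and UC-MSC library 4 held 1187.5 CPM of Cdkn1a (244 to 356). Below their groups lay IRI 24 h library 2 with 641 CPM of Slc34a1 (1065 to 1121) and 72.0 CPM of Slc5a2 (91.9 to 94.8), IRI 72 h library 1 with 9.20 CPM of Ppargc1a (15.6 to 16.01) and Control library 2 with 11.3 CPM of Cdkn1a (20.1 to 21.8). No explanation was tested for single libraries.

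Effects of the same kind differed by a direct test in a pair of comparisons. Changes at 24 h after IRI and sham surgery differed in 4774 genes, and BM-MSC and UC-MSC kidneys in 3402.

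The first pattern weighed is that both MSC groups differed from AKI in many genes, 5552 and 6729. Treatment as the whole cause predicts similar changes against the other untreated group at 6 h. Genes called in BM-MSC against AKI had a median change in the called direction of 1.01. Against IRI 6 h it was 0.146 (0.0442 to 0.259 in single libraries). For UC-MSC these medians were 1.09 and 0.310 (0.216 to 0.365). Genes chosen by their difference from AKI cannot decide this, as AKI also differed from IRI 6 h. A difference between joined blocks remained open, since IRI 24 h, in another block than IRI 6 h, moved by 0.392 in the AKI direction over 5398 of these genes (0.331 to 0.464 in single libraries) and by 0.127 over the others, although those groups also differ in time and the MSC groups' sampling time is not given in the labels.

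The second pattern is the cell cycle list, which was highest at 6 h among the temporal groups. A single library as its source was argued against by a gap of 1.86 between the lowest IRI 6 h library and the highest Control library, wider than the range of 0.729 within Control. Control and the 6 h libraries share a joined block, so the rise over Control is not a difference between blocks. The height of 6 h over the later times cannot be told apart from such a difference, because the fall from 6 to 24 h (median −2.70) runs across the blocks. A wrong time label of the IRI 6 h libraries cannot be told apart from a difference between blocks, because the other group labelled 6 h, AKI, differed at −2.22 but stands in another block. The time after injury remains open as a biological explanation and was not tested apart from these.

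The third pattern is the adrenal list, which was higher with UC-MSC than with BM-MSC. Adrenal tissue taken with some kidneys may account for it, as genes of the adrenal medulla, which are not in the list, were higher too, with a median of 3.63 (Th 4.03, Dbh 3.63, Pnmt 2.94). Th reached a mean of 15.2 CPM, Dbh 5.27 CPM and Pnmt 3.01 CPM in UC-MSC, against 0.282, 0.0703 and 0.225 CPM in BM-MSC. Libraries 2 and 3 carried these UC-MSC means, with Th at 17.7 and 40.9 CPM against 0.439 and 1.83 CPM in libraries 1 and 4. Th also stood at 4.33 and 3.66 CPM in Control libraries 1 and 4. The MSC source as the whole cause cannot be told apart, since the range of the list within an untreated group reached 5.36 (IRI 72 h; 4.77 in AKI and 3.69 in Control) and the groups differed by 4.22.

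Chance as the source of the counts was tested by regrouping the libraries. In each of the 15 comparisons fixed beforehand, only the real split gave as many genes. So few splits argue against chance without excluding it. Counts of the real and the highest other of 35 splits were 3141 and 0 at 6 h, 6986 and 0 at 24 h, 8948 and 1 at 48 h and 9373 and 4 at 72 h. They were 4800 and 507 from 6 to 24 h, 3511 and 75 from 24 to 48 h and 944 and 484 from 48 to 72 h, where the median over the other splits was 176.5. They were 3703 and 1 for sham surgery, 1483 and 0 for BM-MSC against Control, 6172 and 0 for UC-MSC against Control and 3402 and 1308 for UC-MSC against BM-MSC. For IRI 24 h against sham 24 h, the real grouping gave 4774 genes and the highest of 100 drawn regroupings 31. The comparisons with AKI gave 5821 and 2232 against Control, 5552 and 4183 for BM-MSC and 6729 and 4245 for UC-MSC. In each of these the highest other split placed AKI library 1 with 3 libraries of the other group, so the samples hold a structure in which that library sits apart from the rest of AKI. Against IRI 6 h, AKI gave 5800 and 2173 (1 of 35 splits, the real one, gave as many). UC-MSC gave 1954 and 2592 (2 of 35), where the highest split exchanged UC-MSC library 1 and IRI 6 h library 1. BM-MSC gave 0 and 0 (35 of 35). For both MSC groups, splits other than the real one gave as many genes.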

How the results depend on the processing

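The fits that kept disagreeing names and those with IRI 6 h in place of AKI were chosen after the data were examined, and the others before. Across all alternatives, 197 of 219 counts of called genes stayed within 1.5 times the reported one. That held for 15 of 15 with DESeq2 size factors, 15 of 15 without a filter, 14 of 14 with disagreeing names kept, 13 of 15 with DESeq2 and 119 of 128 with a library left out.

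Fitting only the groups compared moved 8 of 15 counts. It gave 7443 genes at 6 h, 11567 at 24 h, 8302 from 6 to 24 h, 24 from 48 to 72 h, 8340 for IRI 24 h against sham 24 h, 3638 for BM-MSC against AKI, 3535 for UC-MSC against AKI and 4970 for BM-MSC against Control. These fits estimate the spread from fewer libraries. DESeq2 called 2001 genes from 48 to 72 h and 2303 for BM-MSC against Control. Leaving out each library gave 1947 to 4212 genes for UC-MSC against BM-MSC and 582 to 1484 for BM-MSC against Control. The cause was not tested.

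With IRI 6 h in place of AKI, edgeR called 0 genes for BM-MSC (215 by DESeq2) and 1954 for UC-MSC. Leaving out single libraries gave 0 to 8 and 499 to 3047. Of genes changed by injury, 0 were then called opposite for BM-MSC (88.8% by sign) and 476 for UC-MSC. With AKI divided in 6 ways, they numbered 2010, 2026, 2036, 1970, 2060 and 2008 for BM-MSC and 1580, 1599, 1664, 1783, 1804 and 1802 for UC-MSC, with fewer libraries in each comparison. DESeq2 gave 4068 and 3209.

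Of 5952 values for named genes, 5638 kept their direction and side of the threshold, 163 became weaker, 59 stronger, 83 moved and 9 reversed. Against IRI 6 h, the BM-MSC changes of Ccnb1 (−0.089), Tfam (0.34) and S100a8 (−0.58) and the UC-MSC changes of Cidea (0.24), Umod (−2.50), Tfam (0.21) and Hmox1 (1.45) took the other sign. Cdkn1a from 6 to 24 h ranged from −0.41 to 0.74, the latter without IRI 6 h library 1, and Hspa1a in UC-MSC against AKI from −1.77 to 2.22, the latter without AKI library 1. The cause was not tested.

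Of 1530 list results, 1169 were unchanged, 251 weaker, 82 stronger, 28 moved and 0 reversed. With an estimated correlation, 217 of 510 were weaker, out of 226 called with the preset one.

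Replicate numbers recur in every group but paired nothing, since no pair of groups had all 4 same-number correlations over 0.1, and the number of libraries that correlated best with their own number lay between 0 and 3 of 4. With the replicate number as a block, 14 of 15 counts stayed within 1.5 times, and the call from 48 to 72 h gave 499 genes. Of 407 named genes, 391 were the same with the block, 9 weaker, 2 stronger and 5 moved. Of 510 lists, 4 became weaker, 7 stronger and 9 moved. Depth was lowest at 72 h, where 15694 to 16501 names had a count against 21073 to 21955 in Control.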

Other observations

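The tests and comparisons here were all chosen after the data were examined, and no explanation was tested. Of the 85 names left out of the temporal and therapy fits, 40 were in the gene lists fixed beforehand. Random draws from 25758 names with a Control count (599 listed) give 1.98 (Fisher's exact test, two-sided, p = 1.37e-42). That assumes independent names of like abundance, but the Control counts of 52 stood under another name. Among the 74 names with differing Control counts, 22 had temporal Control counts that stood under no other name of the therapy table. For 4 of these, including Atp6v1b1, Kap and Mki67, the differing counts kept their last 2 digits. The third Control library held 81 counts of Mki67 in the temporal table and 481 in the therapy table.

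From 24 to 48 h, 15 names with a mean of at least 30 CPM at either time were more than 8-fold higher, and 6 of them were chemokine genes. Of these, Ccl2 and Ccl11 were among the names left out, while Ccl7, Ccl20, Cxcl3 and Cxcl9 were not. The other 9 were Ahdc1, Arhgap11a, Chd9, Crybg2 and 5 predicted genes. Single libraries carried some of these means. Ahdc1 stood at 1470 CPM in IRI 48 h library 4 (others 38.1 to 120) and Crybg2 at 439 CPM in library 2 (0 to 7.20), while Cxcl9 stood at 262 and 281 CPM in libraries 2 and 3 and at 0 and 18.96 CPM in libraries 1 and 4. More than 8-fold lower were 14 names, among them the fat cell genes Adipoq, Cfd and Plin1 and the acute phase genes Fga, Fgb, Fgg, Hp and Saa3. At 72 h, the copies of Ccl2 held 1412, 1906, 1892 and 1375 counts against 22, 19, 22 and 21. Over the names analysed, the predicted gene Gm43305 took 3.62% of the counts at 72 h and Chd9 took 1.23%.

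The 10 most abundant names took 34.0% to 40.4% of the counts in the unoperated sham controls and 45.3% to 52.2% after sham surgery.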
